A study of Komagataeibacter xylinus with 27 samples.

How the data were processed

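RNA was measured in 27 libraries of K. xylinus, 3 for each combination of plasmid label (FNR insert, ArcA insert or empty vector) and oxygen level (15%, 21% or 40%), and each library was placed in its group by its own labels. Per the labels' protocols, ribosomal RNA was removed with probes and libraries were made with dUTP strand marking; per the submitters' processing notes Bowtie2 2.2.3 and HTSeq 0.6.1 were used, and which options were set is not given in the sources used here. The deposited values are FPKM (fragments per kilobase of row length, scaled for library size), 1 column per library, with the name, position, strand, length and description of each row, as the file header names them. No reference genome was used, so gene names, descriptions and positions are those of that table. Of the annotated rows 277 carried a symbol; 802 annotated rows overlapped another on the same strand, where reads could be divided between neighbours, and 154 small RNA rows or rows outside the annotation overlapped a row on the opposite strand, which strand marking keeps apart only if the counting used it.

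FPKM keeps depth when whole reads were counted, so the value of 1 read was worked out for each library from the row lengths. All 80595 values then came within 0.01 of a whole read, and these recovered reads gave the depth: 3432843 to 4962980 per library, with a median of 4261986. Intervals on such reads would cover counting error only. Each mean is given with its SD over 3 libraries, which describes the spread between libraries and is not the error of the mean. The ratio of reads to divisor varied from 0.674 to 1.24, so the deposited FPKM had already been scaled by something other than the summed reads. The median-of-ratios factors given below came out equal, so that scaling was of the median-of-ratios kind. Replicates of a group differed by more than sampling noise in each pair (lowest chi-square per degree of freedom 3.18), so none was treated as a duplicate.

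The main test was fixed before the data were examined, as were the comparisons, the gene lists, the rule for named genes and all alternatives except those called added here. FPKM values were divided by median-of-ratios factors, which came out equal for all libraries (1.01), and 1 was added before taking log2, which understates the change of low genes. Rows at FPKM 1 or more in at least 3 libraries were tested, 2848 of 2985; the 85 annotated rows left out were all transposon, rRNA or tRNA rows. R 4.3.3 with limma 3.58.1 fitted the 9 group means to all 27 libraries (18 residual degrees of freedom) with a trended prior variance, 2-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. There were 16 planned comparisons, 8 of them main: each insert against control at each oxygen level, and 15% and 40% against 21% oxygen in the control. The others were oxygen within each insert strain and the insert by oxygen interactions. The direct difference between the insert strains was added after the data were seen.

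A total of 28 gene lists were matched by product wording (regulators, polysaccharide and sugar metabolism, respiration, stress, iron, translation, transport, mobile elements and others), 26 of which had at least 3 tested rows. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. In the 8 main comparisons 37 list calls were made, of which 1, nitrogen and sulfur uptake for FNR at 15% oxygen, held with an estimated correlation. In simulated data only the iron and TonB uptake list was raised, by log2 0.5. It was found in a share of 0.8 to 1 of the draws with the preset correlation. With an estimated correlation it was found in 0 of them in each of the 16 comparisons, so losing a call there says little about this list. Other lists, of other sizes and levels, were not raised, so what a lost call means for them was not tested. The preset correlation also called 0.2 to 4.2 of the other lists per draw, on average. For FNR at 15%, 21% and 40% oxygen this was 3.4, 1.6 and 1.4, against 2, 9 and 2 lists called in the data. For ArcA it was 1.4, 0.4 and 2.8 against 1, 6 and 6. For 15% and 40% against 21% oxygen in the control it was 4.2 and 0.8 against 6 and 5. Counts adjusted over the list alone used the p-values of the list's own rows.

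Named genes followed a rule. All rows of the cellulose list and the row matched as an insert gene were always allowed. For each main comparison the rule took up to 8 rising and 8 falling genes by absolute log2 change among those past the threshold, with all 3 libraries of a group above the 3 of the other, a mean of at least FPKM 10 in the higher group and a named product, plus up to 4 members per list by p. The other comparisons took up to 3 per direction and 2 per called list. With 3 libraries against 3, chance alone separates 10% of genes in this way. In the data the share over all tested genes was 10.5%, 58.5% and 10.0% for FNR at 15%, 21% and 40% oxygen. For ArcA it was 9.34%, 28.5% and 26.1%, so this condition alone says little. Any gene outside the rule is said to be chosen after its values were seen. The calls followed gene by gene under each alternative are all those taken by the rule, with the genes added to it.

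Tested on simulated data with the real libraries' spread (5 draws per comparison, 200 of 2848 genes changed), the test found 67.2% of genes changed by log2 1 and 94.6% of those changed by log2 2 for 15% against 21% oxygen in the control, but 1 of those draws held 1593 false calls. For the interaction of FNR with 15% oxygen it found 37.6% and 76.2%. A fit with the profile spread as a covariate found more, 93.8% and 99.4% for FNR at 21% oxygen, at a mean share of false calls of 20.6%, its highest of the 16 comparisons. Over them its share ran from 1.20% to 20.6% (median 6.65%), against 0% to 18.4% (median 0.725%) without the covariate, where the highest was for 15% against 21% oxygen in the control. The simulation dealt residual profiles to libraries at random, so the profile spread was not tied to group. In the data its group means differed, as at 21% oxygen (2.22 for FNR against 2.83 in the control). These shares may therefore not hold for the real comparisons. The covariate was chosen after the data were seen, so its counts are given as an alternative.

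Alternatives fixed in advance were no scaling, quantile normalization, pseudocounts of 0.1 and 5, no filter, a mean of at least FPKM 20, the replicate number as a block, a prior variance without a trend, only the libraries compared, camera with an estimated correlation, and each library left out in turn. Added after the data were seen were the profile spread (the interquartile range of a library's log2 values) as a covariate, leaving out the 3 libraries with the narrowest profiles, and voom on the recovered reads. Other splits of the libraries into groups of the same size were counted for every comparison. Correlations across libraries used 100000 resamples. Figures were drawn with Python 3.11.15 and Matplotlib 3.10.9.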

Results

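Komagataeibacter xylinus is an acetic acid bacterium that secretes cellulose as a floating pellicle. The series asked how the regulators FNR and ArcA and the oxygen level affect that cellulose synthesis, and measured RNA from strain CGMCC 2955 carrying the plasmid pSEVA331 with an insert labelled FNR, with an insert labelled ArcA, or empty (the control). In other bacteria FNR is an oxygen-sensing iron-sulfur regulator of the Crp family, and ArcA is the response regulator of a 2-component system that follows the redox state of the membrane. Cultures stood unshaken under 15%, 21% or 40% oxygen. With 3 libraries for each plasmid label and oxygen level there were 27 libraries in 9 groups. The strain label read CGMCC 2955 for 26 libraries and CGMCC 2956 for 1, FNR replicate 2 at 15% oxygen. The table gave FPKM for 2985 rows on 1 sequence, of which 2797 were annotated genes, 146 were transcripts outside the annotation and 42 were small RNAs. Of these, 2848 rows were tested. The reads recovered per library ran from 3432843 to 4962980, with a median of 4261986. Levels are given as mean FPKM ± SD (n = 3 libraries) and fold changes as log2 ± SE on the log2(FPKM + 1) scale, with limma's adjusted p. Nothing in the labels says that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

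The genes of the inserts were looked at first, as a check of the labels. The table held 1 row described as a Crp/Fnr family regulator, CT154_02105 (475347 to 475949, plus strand), and it did not pass the test in any of the 6 insert comparisons. Its level at 15%, 21% and 40% oxygen was 61.0 ± 19.2, 64.0 ± 5.27 and 53.0 ± 19.8 FPKM in libraries labelled FNR, 64.3 ± 4.61, 96.9 ± 39.5 and 101 ± 21.3 in libraries labelled ArcA, and 40.9 ± 38.4, 34.1 ± 7.0 and 45.4 ± 21.7 in the control. The log2 change of CT154_02105 in libraries labelled FNR was 0.90 ± 0.46 (adjusted p = 0.548), 0.91 ± 0.46 (adjusted p = 0.349) and 0.26 ± 0.46 (adjusted p = 1). In libraries labelled ArcA it was 1.02 ± 0.46 (adjusted p = 0.449), 1.42 ± 0.46 (adjusted p = 0.0549) and 1.23 ± 0.46 (adjusted p = 0.121). With the profile spread described below as a covariate it passed at all 3 levels for ArcA, at 0.61, 0.46 and 0.43, and at 15% for FNR, at 0.60. The direct difference between the insert strains passed at no level (0.11, 0.51 and 0.97 ± 0.46; adjusted p = 1, 0.778 and 0.158). No row was named ArcA. CT154_08950 (1944277 to 1944903, minus strand) is annotated with a Crp-like helix-turn-helix domain and a cyclic nucleotide-binding domain. This regulator rose in the libraries labelled ArcA. It reached 6823 ± 384, 5847 ± 3165 and 4301 ± 1112 FPKM there, against 910 ± 333, 979 ± 70.6 and 675 ± 243 in the control and 518 ± 58.4, 530 ± 46.6 and 486 ± 58.0 in libraries labelled FNR. An antisense transcript inside the same gene, Novel00099 (1944289 to 1944875, plus strand), was chosen after its values were seen. It rose with the gene by 2.47 ± 0.20, 2.40 ± 0.20 and 2.61 ± 0.20. Counting that ignored strand would give it about the gene's reads, or almost none. It had 4894 against 19833 in ArcA replicate 1 at 15% oxygen, which argues against that. In libraries labelled FNR, CT154_08950 stood at -0.74, -0.89 and -0.42 (each ± 0.33), passing as lower only with the covariate. Novel00099 passed there as lower at 15% (-0.88 ± 0.20, adjusted p = 0.0334). A regulator with Crp-type domains thus rose in libraries labelled ArcA. The only row described as Crp/Fnr did not pass the main test in either insert strain. Rows were matched by product wording, so others with Crp-type domains were not looked for in libraries labelled FNR. The labels are left in question but not contradicted, since an ArcA insert acting on CT154_08950 cannot be told apart from exchanged names. Both strains are therefore named below by label only and every direction is that of the label.

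**Figure D1:**
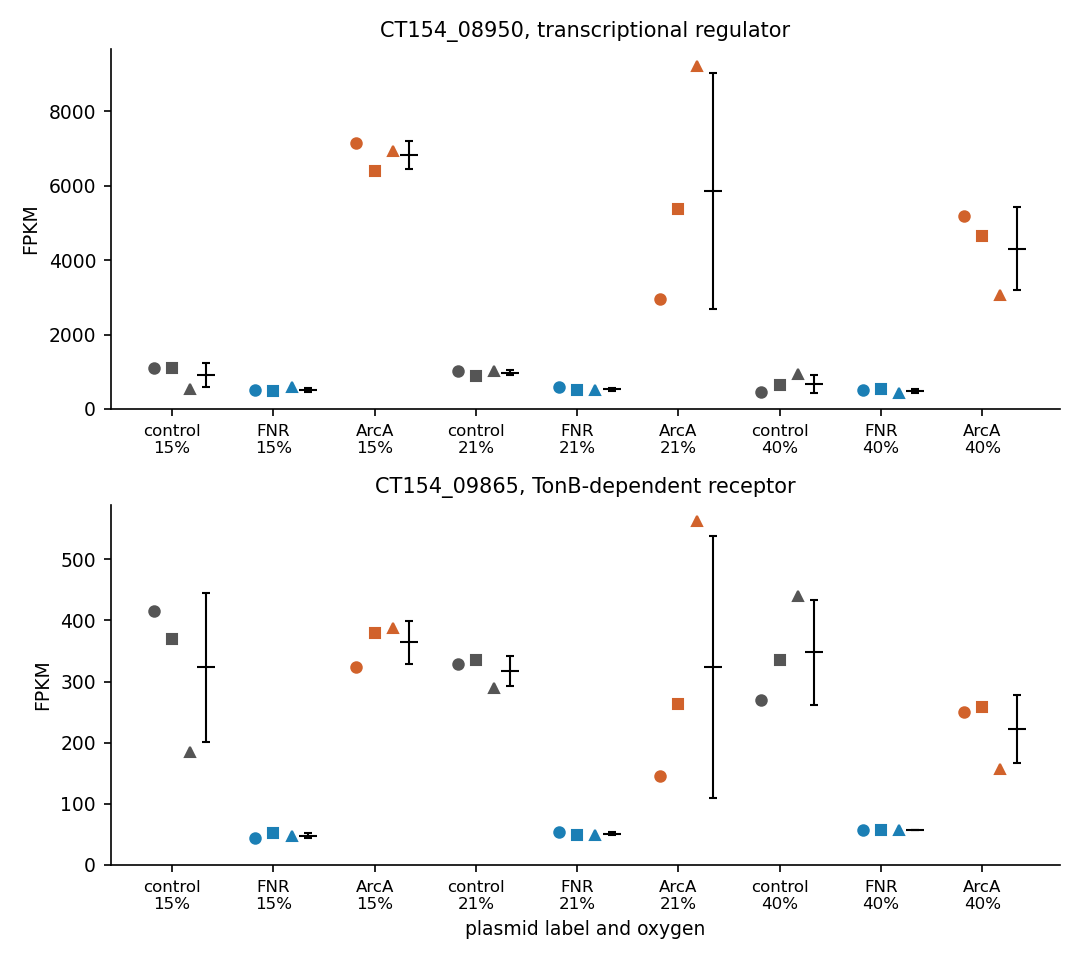
FPKM per library (vertical axes) of the regulator CT154_08950 (top) and the TonB-dependent receptor CT154_09865 (bottom) by plasmid label and oxygen level. Bars are the mean ± SD of 3 libraries and marker shapes give the replicate number. The 9 libraries labelled ArcA lie between 2943 and 9221 FPKM for CT154_08950, above the other 18, and the 3 groups labelled FNR average 47.9 to 57.0 FPKM for CT154_09865.

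Libraries differed in how widely expression was spread over genes. The interquartile range of log2(FPKM + 1) ran from 1.25 to 3.24, and the first principal component, with 70.4% of the variance, followed it (absolute Pearson r of 0.998). At 15%, 21% and 40% oxygen this profile spread averaged 2.38 ± 0.25, 2.22 ± 0.17 and 2.42 ± 0.42 in libraries labelled FNR, 2.28 ± 0.09, 1.98 ± 0.78 and 1.64 ± 0.36 in libraries labelled ArcA, and 2.64 ± 0.95, 2.83 ± 0.20 and 2.35 ± 0.61 in the control. Groups accounted for 38.3% of its variance (permutation test, p = 0.264). Spread rose with the reads recovered, with Pearson r = 0.658 (permutation p = 0.00025) and Spearman rho = 0.658 (permutation p = 0.00029). Without the 2 libraries farthest from the median, r was 0.615. It fell with the FPKM divisor (r = -0.838, rho = -0.826; permutation p = 1e-05 for each, the smallest that 100000 resamples can give; r = -0.813 without the 2 farthest). Adjusted over both relations, the p-values for r were 0.00025 and 2e-05. The divisor was itself a median-of-ratios scale, drawn from the same expression values as the spread. Its relation to the spread is therefore no independent evidence of a technical cause.

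**Figure D2:**
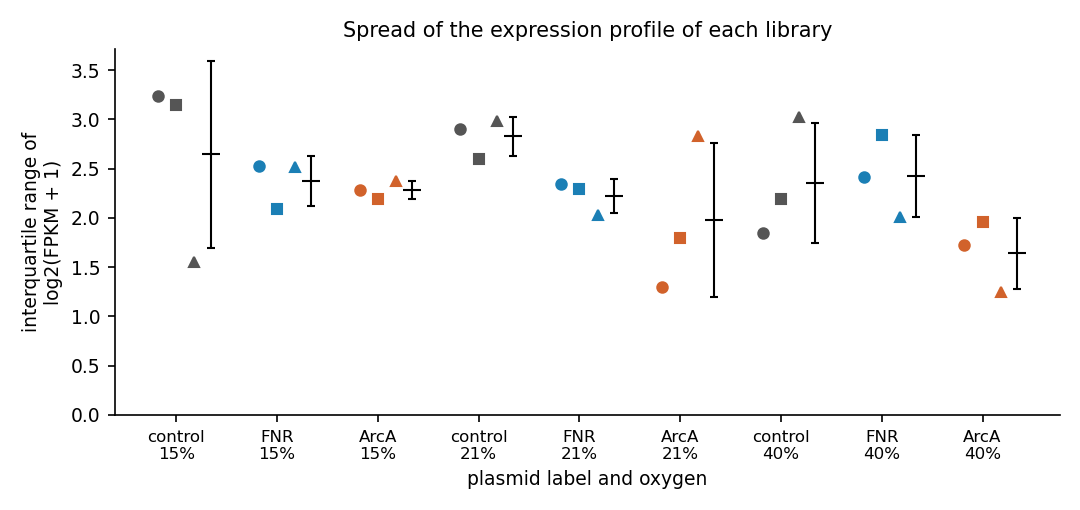
Interquartile range of log2(FPKM + 1) over genes (vertical axis) for each library, by plasmid label and oxygen level; bars are the mean ± SD of 3 libraries. Values run from 1.25 to 3.24, and the control at 15% oxygen alone covers 84.7% of that range.

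At 15% oxygen, the clearest difference between libraries labelled FNR and the control was the loss of CT154_09865 (2172930 to 2175353, plus strand), a TonB-dependent receptor, one of the outer membrane gates through which bacteria take up iron complexes. It fell by 2.65 ± 0.33 on the log2 scale, from 324 ± 122 to 47.9 ± 4.52 FPKM (adjusted p = 0.000271). The T protein gene of the glycine cleavage system, gcvT, rose by 0.84 ± 0.12 (435 ± 7.46 against 245 ± 33.4 FPKM) and gcvP, for its glycine dehydrogenase, by 0.50 ± 0.10 (305 ± 14.4 against 216 ± 20.5 FPKM). So did ssuD, an alkanesulfonate monooxygenase that frees sulfur from organic sulfonates (2.28 ± 0.48; 184 ± 36.0 against 48.2 ± 45.3 FPKM). Further rises were CT154_00255, a 6-hydroxynicotinate monooxygenase (1.64 ± 0.24), CT154_10170, a subunit of D-amino acid dehydrogenase (1.10 ± 0.26; 1218 ± 288 against 580 ± 191 FPKM), and CT154_09330, the PreA subunit of a dihydropyrimidine dehydrogenase (0.66 ± 0.15). The MFS transporters went both ways, with CT154_01600 up by 0.79 ± 0.15 and CT154_10620 at -1.11 ± 0.17. Lower too were the SOS-associated peptidase CT154_07770 (-0.68 ± 0.12), the mechanosensitive channel CT154_09740 (-0.58 ± 0.11) and the succinate-semialdehyde dehydrogenase CT154_09695 (-0.55 ± 0.12). Of the 25 genes of nitrogen and sulfur uptake, 1 rose (ssuD), 0 fell and 21 lay higher, with 2 risen when adjusted over the list alone. The list passed camera (adjusted p = 0.0034; adjusted p = 0.018 with an estimated correlation). Of the 32 genes of the iron and TonB uptake list, 1 rose and 1 fell, the riser being gcvP, a glycine cleavage enzyme picked up by its product wording. Adjusted over the list alone, 5 rose and 1 fell (adjusted p = 0.0034; adjusted p = 0.642 with an estimated correlation), and the iron list lost its call after quantile normalization and with a mean FPKM of at least 20. In all, 29 of 2848 genes passed limma's test, 15 up and 14 down. Of the 17 calls followed gene by gene, 4 held with each library left out, those of CT154_09865, gcvT, CT154_00255 and CT154_10620. Leaving out 1 library moved that count by over 1.5 times in each of the 6 cases, to 10, 19 and 6 without FNR replicates 1, 2 and 3 and to 6, 5 and 231 without control replicates 1, 2 and 3. It was 0 when only these 6 libraries were fitted, 154 after quantile normalization and 555 with the profile spread as a covariate.

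The same receptor led the comparison at 21% oxygen, where CT154_09865 fell by 2.62 ± 0.33 in libraries labelled FNR (50.8 ± 2.60 against 318 ± 24.6 FPKM; adjusted p = 0.000164). The glycine cleavage genes gcvT and gcvP rose here too, gcvT by 0.92 ± 0.12 (435 ± 32.0 against 229 ± 8.29 FPKM) and gcvP by 0.56 ± 0.10. Both subunits of dihydropyrimidine dehydrogenase, the enzyme that starts pyrimidine breakdown, rose, CT154_09330 by 0.91 ± 0.15 and CT154_09335 by 0.75 ± 0.13. So did CT154_00255 (1.54 ± 0.24), the ABC transporter genes CT154_05220 (0.55 ± 0.11) and CT154_05225 (0.54 ± 0.10) and the amino acid permease CT154_02320 (0.63 ± 0.15). Falls included the heat-shock protein gene CT154_11645 (-1.25 ± 0.26; 1043 ± 62.0 against 2484 ± 216 FPKM), the IS110 transposase CT154_07435 (-1.05 ± 0.17), the oxidoreductase CT154_10125 (-0.80 ± 0.13), the aldo/keto reductase CT154_09490 (-0.78 ± 0.16) and CT154_07770 (-0.79 ± 0.12). All 51 ribosomal protein genes lay lower (median -0.49; adjusted p = 3.9e-05), though none passed on its own or when adjusted over the list alone, and the direction turned with the profile spread as a covariate (adjusted p = 0.626). Of 19 heat shock and chaperone genes, 1 fell, 3 when adjusted over the list alone, and all 19 lay lower (median -0.36; adjusted p = 0.000302). All 13 genes of UDP-glucose and sugar nucleotide supply lay lower without a single call (adjusted p = 0.005). Oxidative stress defence (adjusted p = 0.0126) and translation factors (adjusted p = 0.0279; higher with the covariate, adjusted p = 0.626) also lay lower. The other 4 lists past the threshold were efflux (adjusted p = 0.005), iron and TonB uptake (adjusted p = 0.0126), 2-component systems (adjusted p = 0.0279) and conjugation (adjusted p = 0.0279), all higher. With the covariate none of these 9 lists kept its call (7 ended and 2 turned), and after quantile normalization 1 did, UDP-glucose supply. With a mean FPKM of at least 20, 7 of the 9 did, translation factors and conjugation losing theirs. For each of them the adjusted p = 0.631 with an estimated correlation, and the profile spread of the groups was 2.22 ± 0.17 against 2.83 ± 0.20. Of 17 such calls 11 held with each library left out, among them CT154_09865, gcvT, gcvP, CT154_00255, CT154_09330 and CT154_09335. Single genes past limma's test numbered 34, 11 up and 23 down; after quantile normalization the split was 71 up and 70 down. The count was 21 without FNR replicate 2 and 21 without control replicate 3, and it was 1331 when only these 6 libraries were fitted and 266 with the profile spread as a covariate.

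With 40% oxygen, CT154_09865 was again the largest fall among the named genes, at -2.56 ± 0.33 (57.0 ± 0.33 against 348 ± 85.6 FPKM; adjusted p = 0.000471). Another TonB-dependent receptor, CT154_09375, rose by 0.87 ± 0.20. The alanine racemase gene alr rose by 1.29 ± 0.21 (1249 ± 155 against 509 ± 18.3 FPKM) and its neighbour CT154_10170, the D-amino acid dehydrogenase subunit, by 1.63 ± 0.26 (1490 ± 232 against 482 ± 82.9 FPKM). Also up were cysC, the adenylyl-sulfate kinase of sulfate assimilation, by 0.86 ± 0.20, argF, the ornithine carbamoyltransferase of arginine synthesis, by 0.68 ± 0.12, and the acetylornithine transaminase CT154_03965 by 0.78 ± 0.19. CT154_00255 (1.56 ± 0.24), CT154_01600 (0.84 ± 0.15) and gcvP (0.47 ± 0.10) were higher as well. The succinate-semialdehyde dehydrogenase CT154_09695 (-0.63 ± 0.12), the quinone oxidoreductase CT154_09535 (-0.51 ± 0.11), CT154_10125 (-0.63 ± 0.13) and the transposase CT154_07435 (-0.77 ± 0.17) fell. Of the 25 nitrogen and sulfur uptake genes 1 rose and 4 when adjusted over the list alone (adjusted p = 0.0281; adjusted p = 0.0676 with an estimated correlation). No gene of the 9 in glycolysis and gluconeogenesis passed, over all genes or adjusted over the list alone, but 8 lay higher (median 0.27; adjusted p = 0.046; adjusted p = 0.958 with an estimated correlation). This list lost its call with a mean FPKM of at least 20 and with voom. The total was 31 genes, 17 up and 14 down. Of 18 followed calls 5 held with each library left out (CT154_09865, alr, CT154_10170, argF and CT154_00255), and 4 were lost in all 6 cases. Each library left out moved it by over 1.5 times, to 10, 10 and 16 without FNR replicates 1, 2 and 3 and to 16, 12 and 15 without control replicates 1, 2 and 3. It was 2 when only these 6 libraries were fitted, 114 after quantile normalization and 437 with the covariate.

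Among libraries labelled ArcA at 15% oxygen, the rise of CT154_08950 (2.98 ± 0.33; adjusted p = 1.35e-05) was joined by 28 other rises. The OmpA family gene CT154_12470, an outer membrane protein, rose by 1.66 ± 0.29 (1046 ± 84.1 against 333 ± 54.4 FPKM), and the N-acetylglucosaminyltransferase CT154_09580 by 1.31 ± 0.23 (213 ± 12.9 against 85.5 ± 0.58 FPKM). Also up were the glycosyltransferases CT154_09255 (1.22 ± 0.31) and CT154_13385 (1.03 ± 0.22) and the secretion protein CT154_04490 (1.33 ± 0.21). CT154_00480, a bifunctional enzyme that makes or breaks cyclic di-GMP, the messenger that activates cellulose synthase, rose by 0.62 ± 0.14 (214 ± 31.5 against 140 ± 32.0 FPKM). CT154_04365, a transferase that loads UDP-glucose onto a lipid carrier, rose by 0.91 ± 0.20. It lies in a stretch of 14 genes, CT154_04325 to CT154_04390, annotated in large part for exopolysaccharide synthesis and chosen after its values were seen. Of these 8 rose, all 14 with the covariate, and all lay higher (median 0.81), against 1 and 3 risen without ArcA replicates 1 and 2, 4 and 1 without control replicates 1 and 2, and 0 when only these 6 libraries were fitted; it was 12 without the 3 narrowest profiles. In libraries labelled FNR all 14 lay higher than the control here too (median 0.34; 0 risen, 8 with the covariate). From 21% to 15% oxygen all 14 lay lower in the control (median -0.31) with none called, and in libraries labelled ArcA the median was 0.03. The rise over the control uses the same control libraries, and no gene passed the insert by oxygen interactions. The siderophore receptor CT154_02030 (0.98 ± 0.22) and the plasmid mobilization gene CT154_13930 (1.04 ± 0.27) were higher too. Falls were smaller: the malic enzyme CT154_10185 (-0.69 ± 0.17), the transposase CT154_07435 (-0.68 ± 0.17), the channel CT154_09740 (-0.57 ± 0.11), the quinone oxidoreductase CT154_09535 (-0.48 ± 0.11), the peroxide-reducing rubrerythrin CT154_06480 (-0.40 ± 0.09) and the arsenate reductase gene arsC, CT154_10275 (-0.39 ± 0.09). Of the 32 iron and TonB uptake genes 1 rose, 2 when adjusted over the list alone, and 26 lay higher (median 0.38; adjusted p = 0.000538; adjusted p = 0.81 with an estimated correlation). The list lost its call after quantile normalization. Of 22 followed calls 6 held with each library left out, among them CT154_08950, CT154_12470, CT154_09580 and CT154_04490. In total 47 genes passed, 29 up and 18 down, against 65 up and 65 down after quantile normalization. Leaving out ArcA replicates 1, 2 and 3 gave 17, 21 and 31, and leaving out control replicates 1, 2 and 3 gave 20, 16 and 435. The count was 4 when only these 6 libraries were fitted and 531 with the covariate.

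At 21% oxygen in libraries labelled ArcA, CT154_08950 rose by 2.43 ± 0.33 (adjusted p = 0.000304), while the next 3 genes downstream on the same strand fell. The gene on its other side, CT154_08955, stood at 0.38 ± 0.38 (adjusted p = 0.404). CT154_08945, a cyclic di-GMP phosphodiesterase, stood at -1.10 ± 0.28 (506 ± 184 against 1046 ± 108 FPKM). CT154_08940, a GGDEF domain protein of the family that makes cyclic di-GMP, stood at -1.35 ± 0.29 (352 ± 121 against 865 ± 99.4 FPKM) and the Rrf2 family regulator CT154_08935 at -1.52 ± 0.29. In libraries labelled FNR, where CT154_08950 did not rise, CT154_08945 and CT154_08940 lay lower too, at -0.78 ± 0.28 and -1.03 ± 0.29. Neither passed there (adjusted p = 0.19 and 0.0868), though both did with the covariate. The direct difference between the insert strains passed for neither (adjusted p = 0.744 and 0.787). A locus of cytochrome bd oxidase, a respiratory oxidase with high oxygen affinity, fell with its assembly exporter. CT154_07560 (subunit 1) stood at -1.27 ± 0.37, the cydB copy CT154_07565 at -1.10 ± 0.33, the cydD copy CT154_07550 at -0.92 ± 0.21 and the cydC copy CT154_07555 at -0.84 ± 0.20, while the other copies of these 3 names did not pass. The abundant transketolase gene tkt, CT154_08455, of the pentose phosphate pathway fell by 1.21 ± 0.34 (2321 ± 1146 against 4940 ± 275 FPKM). Chaperones fell too, with CT154_11645 at -1.12 ± 0.26, the co-chaperone YbbN gene CT154_00730 at -0.86 ± 0.21 and the DnaJ gene CT154_06860 at -0.67 ± 0.15. Rises included the iron permease CT154_02215 (1.08 ± 0.31), the siderophore receptor CT154_02030 (0.87 ± 0.22), the receptor CT154_09375 (0.76 ± 0.20) and the iron-storing bacterioferritin CT154_02250 (0.69 ± 0.21). Other rises were CT154_00250, a 2Fe-2S protein (1.74 ± 0.48), CT154_00255 (1.25 ± 0.24), the NADP isocitrate dehydrogenase CT154_00570 (0.64 ± 0.18) and CT154_00480 (0.52 ± 0.14). Of the 14 genes CT154_04325 to CT154_04390, 3 rose, 13 with the covariate, and all lay higher (median 0.38), but 11 lay higher after quantile normalization or without ArcA replicate 3. The 3 became 5 without the 3 narrowest profiles, 1 without ArcA replicate 1 or 2 or control replicate 1, and 0 without control replicate 3 or when only these 6 libraries were fitted. Of 56 followed calls 4 held with each library left out, those of CT154_08950, its antisense transcript Novel00099, CT154_08935 and the transposase CT154_07435.

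As groups at 21% oxygen in libraries labelled ArcA, 3 of 19 heat shock and chaperone genes fell, 15 when adjusted over the list alone, and all lay lower (median -0.70; adjusted p = 3.25e-05). This was the only 1 of the 6 lists called here to keep its call and direction with the covariate (adjusted p = 0.00698) or after quantile normalization. Without the 3 narrowest profiles heat shock, iron uptake and efflux kept their calls, and the other 3 lists lost them. Of 32 iron and TonB uptake genes 4 rose (CT154_02030, CT154_02250, CT154_09375 and the glycine cleavage gene gcvP), 5 rising and 2 falling when adjusted over the list alone (adjusted p = 0.0234). Oxidative stress defence lay lower, with 1 of 45 risen (bacterioferritin) and 3 fallen, among them the alkyl hydroperoxide reductase CT154_09700 (-0.96 ± 0.25) and the thioredoxin CT154_13965 (-0.55 ± 0.14). Adjusted over the list alone, 3 rose and 9 fell (adjusted p = 0.0163). Efflux (50 of 59 higher; adjusted p = 0.000108) and 2-component systems (22 of 30 higher; adjusted p = 0.0224) had no single call over all genes or adjusted over the list alone. The 51 ribosomal protein genes lay lower with no call (median -0.44; adjusted p = 0.00466), but higher after quantile normalization (adjusted p = 4.82e-07) and with the covariate (adjusted p = 3.17e-08). With an estimated correlation the ribosomal list had adjusted p = 0.79 and the other 5 lists adjusted p = 0.71. The profile spread was 1.98 ± 0.78 in libraries labelled ArcA against 2.83 ± 0.20. Over single genes limma called 230, 66 up and 164 down, against 194 up and 208 down after quantile normalization. The count was 30, 47 and 1785 without ArcA replicates 1, 2 and 3, 33 and 19 without control replicates 1 and 3, and 0 when only these 6 libraries were fitted. With the covariate 386 genes passed, 195 of the 230 among them.

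Under 40% oxygen the libraries labelled ArcA had CT154_08950 up by 2.70 ± 0.33 (adjusted p = 7.11e-05) and, as at 21%, the cyclic di-GMP genes CT154_08940 and CT154_08945 down, at -1.18 ± 0.29 and -1.06 ± 0.28. In libraries labelled FNR these genes stood at -0.52 ± 0.29 and -0.38 ± 0.28 without passing, and both passed as lower with the covariate. The genes of both steps from pyruvate to acetoin, a neutral overflow product, fell, with the acetolactate decarboxylase gene budA at -1.26 ± 0.32 (348 ± 69.5 against 841 ± 200 FPKM) and the acetolactate synthase AlsS gene CT154_01270 at -0.63 ± 0.14. None of the 14 genes CT154_04325 to CT154_04390 passed (median 0.19), though 7 rose after quantile normalization and 4 with the covariate. Malic enzyme CT154_10185 fell by 0.89 ± 0.17 (262 ± 25.3 against 494 ± 105 FPKM; adjusted p = 0.00874), as did the alkyl hydroperoxide reductase CT154_08150 (-0.88 ± 0.21), the lysine pathway enzyme CT154_06925 (-0.92 ± 0.23), the dioxygenase subunit CT154_03880 (-1.13 ± 0.28) and the ligase CT154_11390 (-1.21 ± 0.31). Rises were few, with metW, of methionine synthesis, at 0.82 ± 0.21, the transporter CT154_01970 at 0.55 ± 0.13 and the cysteine tRNA ligase CT154_12535 at 0.45 ± 0.11. Of 19 heat shock genes 1 fell (CT154_06860), 6 when adjusted over the list alone (median -0.62; adjusted p = 0.000251). Of 20 cytochrome oxidase and bc1 genes none passed over all genes and 4 fell when adjusted over the list alone (adjusted p = 0.0405). Oxidative stress defence lay lower, with 1 of 45 fallen, and 1 risen and 3 fallen when adjusted over the list alone (adjusted p = 0.00442). Efflux (1 of 59 risen, also 1 when adjusted over the list alone; adjusted p = 0.000251) and 2-component systems (no call; adjusted p = 0.00236) lay higher. The 51 ribosomal genes lay lower with no call (adjusted p = 0.000251), but higher after quantile normalization (adjusted p = 0.00537) and with the covariate (adjusted p = 0.0269). With the covariate none of the 6 lists kept its call, heat shock standing at adjusted p = 0.202, and after quantile normalization 2 did, the cytochrome oxidases and the 2-component systems. The cytochrome list lost its call with a mean FPKM of at least 20 and with voom. All 6 had adjusted p = 0.706 with an estimated correlation, and the profile spread was 1.64 ± 0.36 against 2.35 ± 0.61. Of 21 followed calls 2 held with each library left out, those of CT154_08950 and Novel00099. In all 61 genes passed, 8 up and 53 down, against 137 up and 160 down after quantile normalization. Without ArcA replicates 1, 2 and 3 the count was 14, 34 and 8, and without control replicates 1, 2 and 3 it was 125, 18 and 7. It was 1 when only these 6 libraries were fitted, 28 without a trend in the prior variance and 379 with the covariate.

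Between oxygen levels in the control strain, the genes that rose lay mostly in 1 stretch. At 40% against 21% oxygen the glycosyltransferases CT154_04380 and CT154_04370 rose by 1.17 ± 0.21 and 1.16 ± 0.15 (414 ± 45.1 against 184 ± 24 FPKM and 354 ± 29.98 against 158 ± 13.1 FPKM). So did CT154_04375, annotated as the succinoglycan protein ExoP, by 1.16 ± 0.17 (384 ± 33.8 against 172 ± 20.9 FPKM), and the flippase CT154_04385 by 1.10 ± 0.21. The glycosyltransferases CT154_04350 (1.01 ± 0.15) and CT154_04345 (0.96 ± 0.17) and the UDP-glucose lipid carrier transferase CT154_04365 (0.94 ± 0.20) rose with them. Of the 14 genes from CT154_04325 to CT154_04390 (964021 to 983596), a stretch chosen after its values were seen, 11 rose, all 14 with the covariate, and all lay higher (median 0.93). The exopolysaccharide list fixed in advance was not called (0 of 7 risen, 2 when adjusted over the list alone; adjusted p = 0.124), nor was UDP-glucose supply (1 of 13 risen, 3 when adjusted over the list alone; adjusted p = 0.289), though the latter passed with the covariate. Outside the stretch rose the acetoin dehydrogenase subunit CT154_04275 (1.03 ± 0.21), the ABC transporter protein CT154_04265 (1.01 ± 0.19) and the cyclic di-GMP enzyme CT154_00480 (0.78 ± 0.14; 284 ± 12.7 against 164 ± 13.2 FPKM). The calls of CT154_04350, CT154_04370 and CT154_04375 held with each library left out. The total was 15 genes, all up. It was 4 and 3 without the 21% replicates 2 and 3, 5 without the 40% replicate 3, 5 when only these 6 libraries were fitted and 44 (37 up) with the covariate. Of the lists, iron and TonB uptake (25 of 32 higher; adjusted p = 0.0177) and efflux (45 of 59 higher; adjusted p = 0.0115) lay higher, and heat shock (all 19 lower; adjusted p = 0.000492) and translation factors (5 of 33 higher; adjusted p = 0.0309; with the covariate the test turned at a median of -0.01) lay lower. None of these lists had a member called over all genes or adjusted over the list alone, and each had adjusted p = 0.711 with an estimated correlation. Ribosomal genes lay lower (adjusted p = 0.00188; adjusted p = 0.747 with an estimated correlation), but higher after quantile normalization (adjusted p = 0.0854) and with the covariate (adjusted p = 0.0222). Of these 5 lists 1, iron and TonB uptake, kept its call with the covariate (adjusted p = 0.0403) and none did after quantile normalization.

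**Figure D3:**
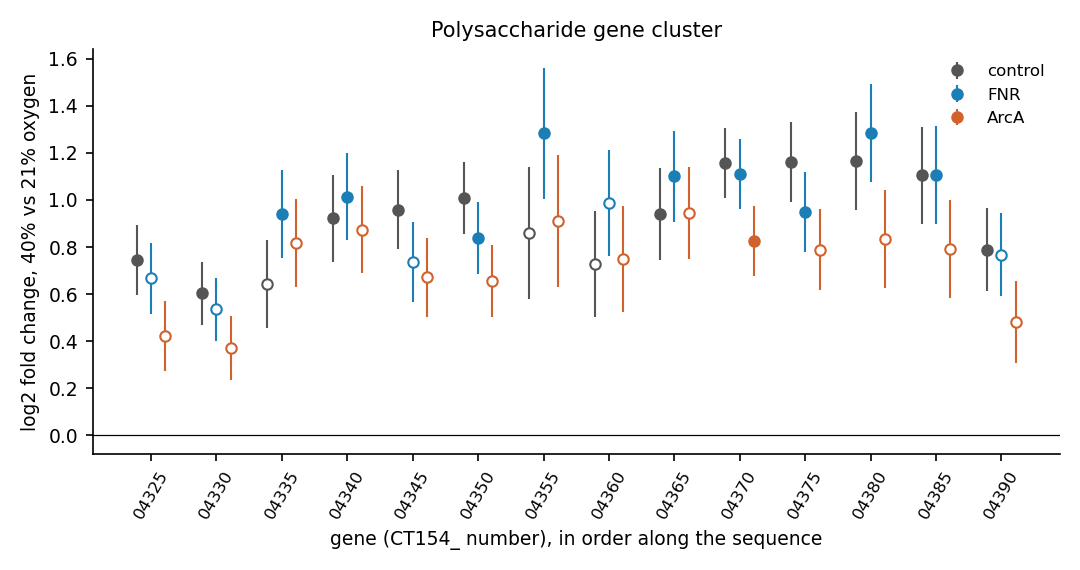
Log2 fold change ± SE at 40% against 21% oxygen (vertical axis) of the 14 genes CT154_04325 to CT154_04390 in the control and in libraries labelled FNR and ArcA. Filled symbols mark an adjusted p under 0.05 and open symbols the others: 11, 9 and 1 genes passed, against 14, 14 and 13 with the profile spread as a covariate, and all 14 lay higher for each plasmid.

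Lowering oxygen from 21% to 15% in the control moved no single gene past the test. By limma 0 genes passed, 23 had an unadjusted p under 0.05, and voom on the recovered reads also gave 0. The UDP-glucose and sugar nucleotide genes (1 of 13 higher; adjusted p = 0.00213), heat shock (all 19 lower; adjusted p = 0.00203), cytochrome oxidases (4 of 20 higher; adjusted p = 0.0319) and ribosomal proteins (1 of 51 higher; adjusted p = 0.028) lay lower. By contrast 2-component systems (23 of 30 higher; adjusted p = 0.0306) and efflux (43 of 59 higher; adjusted p = 0.0431) lay higher. None of these lists had a member called over all genes or adjusted over the list alone, and with an estimated correlation the ribosomal list had adjusted p = 0.904 and the other 5 adjusted p = 0.825. Without control replicate 3 at 15% oxygen, whose spread of 1.55 was the third narrowest, heat shock (adjusted p = 0.151), UDP-glucose (adjusted p = 0.653) and ribosomal genes (adjusted p = 5.26e-05) turned to higher, and 2-component systems (adjusted p = 0.66) and efflux (adjusted p = 0.0207) to lower. Ribosomal genes also turned after quantile normalization (adjusted p = 0.000213). With the covariate, as after quantile normalization, 2 of the 6 lists kept their call and direction, UDP-glucose and heat shock, and without the 3 narrowest profiles none did.

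Genes of the same stretch also rose at 40% oxygen in the insert strains. In libraries labelled FNR, CT154_04355, a UDP-glucose or GDP-mannose dehydrogenase, rose by 1.28 ± 0.28 (801 ± 110 against 327 ± 26.1 FPKM), CT154_04380 by 1.28 ± 0.21, CT154_04370 by 1.11 ± 0.15, CT154_04365 by 1.10 ± 0.20 and CT154_04335, annotated as GumK of xanthan synthesis, by 0.94 ± 0.19. Of its 14 genes 9 rose, 14 with the covariate, CT154_04370 with each library left out, and 10 genes rose in all with none lower. In the UDP-glucose list 2 of 13 rose, 3 when adjusted over the list alone (adjusted p = 6.43e-10; adjusted p = 0.337 with an estimated correlation). In the exopolysaccharide list 1 of 7 rose, 2 when adjusted over the list alone (adjusted p = 0.0212; adjusted p = 0.218 with an estimated correlation; adjusted p = 0.0571 with the covariate), a call also lost when only these 6 libraries were fitted. The gene count was 2 and 6 without the 21% replicates 2 and 3, 1 without the 40% replicate 2 and 40 with the covariate. In libraries labelled ArcA, 3 genes rose between 21% and 40% oxygen: CT154_00480 by 0.78 ± 0.14 (411 ± 75.6 against 236 ± 13.3 FPKM), CT154_04370 by 0.83 ± 0.15 (391 ± 93.6 against 217 ± 29.9 FPKM), and the hypothetical protein CT154_08485 by 0.63 ± 0.12, named after its values were seen. Of the 14 genes of the stretch, 13 passed in them with the covariate. In their UDP-glucose list 0 of 13 passed over all genes and 3 rose when adjusted over the list alone (adjusted p = 0.0249; adjusted p = 0.652 with an estimated correlation). The list turned to lower without ArcA replicate 1 at 21% (adjusted p = 0.935), and its call was lost with voom, without the 3 narrowest profiles and when only these 6 libraries were fitted. The count of 3 was 0 without ArcA replicate 1 or 2 at either level, 9 without the 21% replicate 3, 11 without the 40% replicate 3, 47 (29 up, 18 down) after quantile normalization and 46 with the covariate.

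From 21% to 15% oxygen no single gene passed in either insert strain. In libraries labelled FNR limma called 0, with 30 at an unadjusted p under 0.05 and 0 by voom, and 1 without FNR replicate 1 at 15%. Quantile normalization gave 3 (1 up, 2 down) and the covariate 7 (all down). Nitrogen and sulfur uptake lay higher there, with 18 of 25 genes higher and no call, over all genes or adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.0368 with an estimated correlation), a call lost when only these 6 libraries were fitted. In libraries labelled ArcA limma called 0, with 96 at an unadjusted p under 0.05 and 0 by voom. Of 26 lists, 3 passed for FNR and 6 for ArcA at 15% oxygen and 5 and 10 at 40%, and with an estimated correlation 1 of them passed, nitrogen and sulfur uptake in libraries labelled FNR. Whether the insert's effect differed between oxygen levels was tested as an interaction, and limma called 0 genes in each of the 4 tests. At an unadjusted p under 0.05 there were 10 and 61 for FNR (15% and 40% against 21%) and 88 and 14 for ArcA, and voom gave 0 in all 4. So no difference in an insert's effect between oxygen levels is shown for a single gene, including those called at 1 level only.

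Genes of cellulose synthesis did not pass the test in any comparison, though some did under other settings. The 11 genes of the list were 4 bcsA rows (CT154_12695, CT154_03760, CT154_05660 and CT154_04230), which encode the catalytic subunit, the BcsB gene CT154_12690, 4 more rows named cellulose synthase (CT154_12680, CT154_12685, CT154_05665 and CT154_04245) and the endoglucanases CT154_12700 and CT154_12705, which trim cellulose chains. In each of the 16 comparisons 0 of the 11 passed limma, over all genes or adjusted over the list alone. The bcsA gene of the highly expressed operon, CT154_12695, stood at 1144 ± 505, 1333 ± 110 and 1050 ± 354 FPKM in the control at 15%, 21% and 40% oxygen, at 1078 ± 169, 1042 ± 112 and 1078 ± 230 in libraries labelled FNR, and at 1054 ± 73.0, 840 ± 508 and 551 ± 184 in libraries labelled ArcA. Against the control its log2 change was 0.02 ± 0.38, -0.36 ± 0.38 and 0.07 ± 0.38 for FNR, and 0.00 ± 0.38, -0.85 ± 0.38 (adjusted p = 0.106) and -0.94 ± 0.38 (adjusted p = 0.14) for ArcA. The bcsA row CT154_03760 came closest, at -0.48 ± 0.18 for ArcA at 21% oxygen (adjusted p = 0.0756). Without ArcA replicate 3 at 21% oxygen, where 1785 genes passed, all 11 did (7 lower, 4 higher), and when only the 6 libraries of FNR at 21% were fitted, where 1331 passed, 9 did (7 lower, 2 higher). Between 1 and 3 passed with the covariate, after quantile normalization, without the 3 narrowest profiles or without control replicate 3 at 15% in some comparisons of an insert with the control. The list's camera test gave adjusted p = 0.742, 0.863 and 0.649 for FNR, 0.856, 0.469 and 0.407 for ArcA, and 0.656 and 0.345 for 15% and 40% against 21% oxygen in the control. It passed after quantile normalization for FNR at 15% (adjusted p = 0.0317, higher). In simulated data of the same spread the test found 64.8%, 62.6% and 64.0% of genes changed by log2 1 for FNR and 65.4%, 59.6% and 62.6% for ArcA, and missed the rest. Smaller changes were not simulated. Those shares are over all the genes changed in the simulation, so they do not give the share for cellulose genes. The median SE over tested genes was 0.25, against 0.38 for CT154_12695 and 0.18 for CT154_03760. For CT154_12695, changes of -0.85 and -0.94 did not pass, so a change near log2 1 in it could be missed. The simulation also changed more genes than limma called here, except for ArcA at 21% oxygen, which makes the adjustment less strict.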

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

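The tests of the profile spread other than that of depth, the tests of CT154_08950, those with the covariate, and the direct differences between the insert strains were chosen only after the results were seen; the counts of splits and the depth test were set beforehand.

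Differences between groups were what drew attention to the following results, each from a test of the difference itself. Between the insert strains (ArcA minus FNR), 46 genes differed at 15% oxygen (30 higher, 16 lower, against 77 and 96 after quantile normalization), 44 at 21% (28 and 16, against 98 and 131) and 181 at 40% (21 and 160, against 104 and 228). At 21% the count was 7 without FNR replicate 1, 8 without FNR replicate 2 and 7 without ArcA replicate 2; at 40% it was 25 and 6 without FNR replicates 1 and 2, and 82 and 13 without ArcA replicates 1 and 3. CT154_08950 differed between them by 3.72 ± 0.33, 3.31 ± 0.33 and 3.11 ± 0.33 (log2, limma). Gene lists passed camera in the insert by oxygen interactions, 6 and 10 for FNR at 15% and 40% against 21%, and 6 and 1 for ArcA. With an estimated correlation 0 of them did so, a setting that also missed the only list raised in simulated data.

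A first pattern is the narrow expression profile of some libraries, with interquartile ranges of 1.25, 1.30 and 1.55 in ArcA replicate 3 at 40%, ArcA replicate 1 at 21% and control replicate 3 at 15% oxygen, against 3.24 in the widest. Lower depth is argued against, since thinning the widest library to the lowest total left its range at 3.23, and the group cannot be the whole cause, since the control at 15% oxygen alone spanned 84.7% of the range of all libraries. An even background of reads, as genomic DNA would give, would flatten low genes more than high ones, but the slope against the other libraries differed by 0.0943, 0.0416 and at the least -0.0129 between genes above FPKM 500 and genes at FPKM 20 to 100, which argues against it as the whole cause. A set of 47 mobile element and plasmid genes was chosen for low levels in the widest libraries. Its median was 67.0, 58.4 and 41.0 FPKM in the 3 narrowest libraries against 12.7 in the widest. That choice, and any narrowing of the profile, would give such a contrast, so it decides nothing about a background. An uneven background, RNA breakdown or a different growth state of single cultures may each be involved; none of these was tested.

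Secondly, CT154_08950, with its Crp-type domains, was high in the libraries labelled ArcA. A few mislabelled libraries cannot account for it, because all 9 libraries labelled ArcA (2943 to 9221 FPKM) lay above the highest of the other 18 (1104 FPKM). Extra copies of this region on the plasmid are a candidate explanation: the next gene downstream, 23 bp away, did not rise at any level (highest log2 change -0.53), which induction of this gene alone would give as well. The antisense transcript Novel00099 lies wholly inside the gene, so counting that ignored strand would give it about the gene's reads, or almost none. It had 4894 reads against 19833 in ArcA replicate 1 at 15% oxygen and 817 against 1578 in control replicate 3 at the same level. That argues against such counting at this gene. How well the strand marking worked was not checked, so the transcript's rise decides nothing on the cause. Whether the names FNR and ArcA were exchanged as a whole cannot be told apart from an ArcA insert that acts on this gene. Of 30 two-component genes 0 rose by over 1 at all 3 levels in libraries labelled FNR (the highest reached 0.19 at its lowest level). The only row described as Crp/Fnr, CT154_02105, stood at 1.02, 1.42 and 1.23 for ArcA and 0.90, 0.91 and 0.26 for FNR without passing in either. Reads of an insert from another organism may be missing here, which could not be checked. The biological reading, that the ArcA label is right and the regulator is induced by it, stays open and untested.

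The third pattern is that calls moved with the profile spread. With the spread as a covariate 195 of the 230 calls for ArcA at 21% oxygen remained (84.8%), which argues against the spread as their whole cause, but their median absolute log2 change fell from 0.79 to 0.43 and they passed because the median SE fell from 0.20 to 0.10. The 35 that ended shrank as much, from 0.78 to 0.45, and differed in that their median SE fell only from 0.24 to 0.15. Of the 37 list calls in the 8 main comparisons, 28 ended or turned (75.7%), as an effect of the spread on lists of abundant or rare genes would predict, and 9 kept their side, so those 28 may follow the spread and not the plasmid or oxygen. Lists were also gained. With the covariate 4, 2 and 2 lists passed for FNR at 15%, 21% and 40% oxygen, and 5, 6 and 3 for ArcA. For 15% and 40% against 21% oxygen in the control it was 5 and 4. Of these 2, 0 and 2, then 1, 2 and 1, then 2 and 2 had also passed without it. Without the 3 narrowest profiles 12, 11 and 2, then 7, 3 and 6, then 9 and 5 lists passed. The covariate can also take away real effects that go with the spread, and no biological explanation was tested here.

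Other splits of the same libraries were counted for each comparison. For each of the 12 comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts were 29, 34 and 31 for FNR, 47, 230 and 61 for ArcA, 15 for 40% oxygen in the control, 10 in FNR and 3 in ArcA, each given by 1 of the 10 splits with 0 as the highest other; the 15% against 21% comparisons had 0 in all 10 splits. For the 4 interactions, 100 of 100 splits gave at least the real 0, which holds for any data and says nothing about chance. The highest of the others were 1336 and 101 genes for FNR at 15% and 40%, and 2087 and 1799 for ArcA, well above the real 0. A structure of the samples apart from the groups may be involved, as may the mixing of groups that differ, and neither was tested.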

How the results depend on the processing

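The covariate, the fit without the 3 narrowest profiles, voom and the direct difference between the insert strains were chosen after the data were seen; the other alternatives were set beforehand. No scaling gave nearly identical values because the scaling factors were equal, so it tests nothing. Of 191 calls taken by the rule for named genes or added to it, 148 were lost when only the libraries compared were fitted, 53 with the replicate block, 49 with quantile normalization, 23 without a trend, 20 without the 3 narrowest profiles, 19 with voom, 8 with the covariate and 3 or fewer under each other setting. Leaving out 1 library lost 585 of 1146. Of these called genes, CT154_12625 and CT154_13035 for ArcA at 21% turned direction, after quantile normalization (0.062 and 0.098). Of 97 results of genes not called, 59 turned sign under at least 1 setting. Of the counts of genes called, those not listed here stayed within 1.5 times under that setting. The cause of the moves was not tested, except that smaller fits have fewer libraries.

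Counts are given for FNR at 15%, 21% and 40%, then ArcA at 15%, 21% and 40%. Quantile normalization moved them to 154, 141, 114, 130, 402 and 297, FNR at 15% against 21% oxygen to 3 and ArcA at 40% against 21% to 47. The covariate gave 555, 266, 437, 531, 386 and 379, then 44, 40 and 46 for 40% against 21% in control, FNR and ArcA, and 7 for 15% against 21% in FNR. Without the 3 narrowest profiles FNR gave 605, 202 and 55, ArcA at 15% 763, and 40% against 21% oxygen 28, 19 and 12. Fitting only the libraries compared gave 0, 1331, 2, 4, 0 and 1, and for 40% against 21% 5 in the control and 0 in ArcA. Without a trend ArcA at 40% gave 28, and voom gave 1 for ArcA at 40% against 21%. For ArcA minus FNR at 15%, 21% and 40%, quantile normalization gave 173, 229 and 332, the covariate 395, 489 and 333, and only the libraries compared 113, 0 and 7; without the 3 narrowest it gave 98 and 74 at 15% and 21%.

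The replicate numbers did not pair the libraries: in 0 of 12 comparisons did all 3 pairs correlate over 0.1, the median correlation was -0.038 for the same number and 0.010 for another, and 4 of 27 libraries correlated best with their own number. The replicate block moved ArcA at 40% to 19, ArcA at 40% against 21% to 0, and ArcA minus FNR at 21% and 40% to 20 and 78, with no other count moved by over 1.5 times.

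Leaving out 1 library gave, from lowest to highest, 5 to 231 for FNR at 15%, 21 to 33 at 21% and 10 to 16 at 40%; 16 to 435, 19 to 1785 and 7 to 125 for ArcA; 3 to 11 for 40% against 21% in the control, 1 to 10 in FNR and 0 to 11 in ArcA; 0 to 1 for 15% against 21% in FNR and 0 to 0 in the control and ArcA; and 0 to 0 for the interactions. ArcA minus FNR ran from 31 to 42, 7 to 47 and 6 to 234.

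Among the lists, after quantile normalization ribosomal genes turned for ArcA at 21% (adjusted p = 4.82e-07) and 40% (0.00537) and for 15% (0.000213) and 40% (0.0854) against 21% in the control. With the covariate they turned for FNR at 21% (0.626), ArcA at 21% (3.17e-08) and 40% (0.0269), and 15% (0.947, with a median of -0.05) and 40% (0.0222) in the control, as did translation factors for FNR at 21% (0.626) and 40% in the control (0.883, with a median of -0.01). For 15% against 21% in the control, 2-component systems, UDP-glucose, heat shock, ribosomal and efflux lists turned without the 3 narrowest profiles (0.622, 0.622, 0.155, 6.71e-07 and 0.0155) and without control replicate 3 at 15% (0.66, 0.653, 0.151, 5.26e-05 and 0.0207). The UDP-glucose list for ArcA at 40% against 21% turned without ArcA replicate 1 at 21% (0.935). Over single libraries left out, those 5 lists ranged from 0.00858 to 0.66, 0.000414 to 0.653, 7.86e-05 to 0.151, 5.26e-05 to 0.0966 and 0.00242 to 0.462, and this one from 3.43e-12 to 0.935. Depth, at 3432843 reads in the smallest library, left low genes imprecise, and 3 libraries per group limit the rest.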

Other observations

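The genes named here were chosen after their values were seen, from the direct difference between the insert strains (ArcA minus FNR), a comparison added after the data were seen.

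A run of 3 neighbouring genes for the breakdown of purines by way of urate and allantoin was lower in libraries labelled ArcA than in those labelled FNR at all 3 oxygen levels. For uraH, hydroxyisourate hydrolase, the difference was -0.67 ± 0.10, -0.58 ± 0.10 and -0.49 ± 0.10 (log2 ± SE) at 15%, 21% and 40% oxygen, with limma's adjusted p = 0.000181, 0.0032 and 0.00786. The next step, uraD (OHCU decarboxylase), stood at -0.79 ± 0.15, -0.71 ± 0.15 and -0.80 ± 0.15 (adjusted p = 0.00505, 0.0288 and 0.00692). CT154_11725, the allantoinase PuuE, stood at -0.76 ± 0.18, -0.78 ± 0.18 and -0.85 ± 0.18 (adjusted p = 0.0317, 0.035 and 0.0122). In FPKM, uraD averaged 509 ± 28.3, 455 ± 25 and 437 ± 63.3 in libraries labelled FNR, 293 ± 14.1, 282 ± 55.0 and 250 ± 33.5 in those labelled ArcA, and 341 ± 70.5, 369 ± 33.1 and 333 ± 40.6 in the control (SD, n = 3), so the control's mean lay between the 2 at each level. Of the 6 single libraries left out, the call was lost in 0, 0 and 2 cases for uraH, 0, 4 and 2 for uraD and 5, 5 and 3 for CT154_11725.

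Other genes differed the other way. The receptor CT154_09865 was higher in libraries labelled ArcA by 2.90 ± 0.33, 2.44 ± 0.33 and 1.91 ± 0.33 at 15%, 21% and 40% oxygen (adjusted p = 2.13e-05, 0.000203 and 0.0051). The OmpA family gene CT154_12470 was higher by 2.49 ± 0.29, 1.51 ± 0.29 and 1.00 ± 0.29 (adjusted p = 2.3e-05, 0.015 and 0.0463), and the glycosyltransferase CT154_13385 by 1.56 ± 0.22, 0.91 ± 0.22 and 0.91 ± 0.22 (adjusted p = 0.000139, 0.0408 and 0.0241). CT154_09865 kept its call with each library left out, while CT154_12470 lost it in 0, 3 and 6 of the 6 cases and CT154_13385 in 0, 5 and 4. CT154_08975, a bifunctional diguanylate cyclase and phosphodiesterase, was higher by 2.08 ± 0.28 at 15% oxygen (1732 ± 222 against 409 ± 59.1 FPKM; adjusted p = 0.000102). It missed the threshold at 21% (1.03 ± 0.28; adjusted p = 0.0761) and 40% oxygen (0.31 ± 0.28; adjusted p = 0.362), and whether these differences themselves differ between levels was not tested.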
